A study of Homo sapiens with 28 samples.

How the data were processed

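The experiment used HEK293T cells, a human embryonic kidney line, that carried 2 RNA-editing enzymes at the same time, each tethered to a reader of N6-methyladenosine (m6A). In TRIBE, a reader is fused to the catalytic domain of ADAR, which changes adenosine to inosine, read as G. In STAMP, a reader is fused to APOBEC1, which changes cytidine to uridine, read as T. The readers were YTHDF1, YTHDF2 and YTHDF3. Per the labels' protocols, cells with a stable, doxycycline-inducible YTHDF-APOBEC1 fusion (1 ug/mL for 24 h) were transfected with a YTHDF-ADAR plasmid for 24 h, and poly(A) RNA was made into stranded libraries. Reads were paired, of 150 and 250 bp.

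There were 28 libraries. Of these, 24 held 1 ADAR and 1 APOBEC1 fusion in 9 combinations, with 3 libraries for each combination with YTHDF1-ADAR or YTHDF2-ADAR and 2 for each with YTHDF3-ADAR. A further 2 held APOBEC1 alone and 2 held ADAR alone. In 16 of the 24 libraries the label for the transfected plasmid named another ADAR fusion than the title. The titles were used, because the description and the design text matched them.

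The authors deposited 6 lists of edited sites, 1 per fusion, each pooled over the libraries with that fusion (9, 9 and 6 for YTHDF1-, YTHDF2- and YTHDF3-ADAR, and 8 for each APOBEC1 fusion). Reads were aligned with STAR 2.7.7 to GRCh38, per the submitters' processing notes. The site caller, its filters and the pooling are not given in the sources used here. Each line of the deposited lists has a position, a gene name, a strand and a value taken here as the editing level, a fraction of reads at the site. That unit was read from the values, which run from 0.05 to 0.981 and have no header. All 6 lists start at 0.05. Per the labels' design text, cells with ADAR or APOBEC1 alone served as controls, 1 set per deaminase. How they entered the calling is not given in the sources used here. Read depth per site or library, levels per library and levels in the controls were not analysed here. The lists therefore have no replicate spread, no test of a site was run, and intervals cover counting error or the sampling of genes only.

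Sites were matched by chromosome, position and strand. Sites on a vector sequence (11, 2 and 0 in the ADAR lists and 2, 1 and 1 in the APOBEC1 lists) were set apart. Gene names were matched to a RefSeq table of GRCh38.p14. Of 15734 names, 13846 matched by symbol and 260 by a synonym, together 89.7%. That table gives gene spans without exons. The planned shares of sites in 3′ UTRs, coding sequence and introns, and the search for the m6A motif, were therefore not run. In their place stands the share of sites in the last 2 kb of the span of protein-coding genes, a measure chosen after seeing the data.

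Overlap of sites is the share of the shorter list found in the other list, with a Wilson 95% interval. Overlap of genes is the observed number of shared genes over n1 × n2 / N, where N holds the genes with a site in any list of the other deaminase. Levels at shared sites were compared per site, with a 95% bootstrap interval over genes (1000 draws). Same-reader and other-reader pairs across the deaminases were compared after every list was thinned to the shortest (100 draws), with an exact permutation of the 3 reader names (6 orders, two-sided). Its smallest p is 1/6 in one direction, so no value under 0.05 could be had. For 15 gene lists fixed before the data were examined, the share of genes with a site was set against 10000 random lists of genes with a site in any of the 6 lists, matched on gene span in 10 bins. Exonic length had been planned for that matching and needs exons. The gene names given below follow rules fixed at the same time. These were the 10 genes with the most sites per list, and the 5 genes each way with the largest difference per 10000 sites between readers. The 10 genes with the highest minimum over the 6 lists, up to 4 members of each gene list and the genes of the readers and of ADAR and APOBEC1 enzymes were added. The rule for single sites needed read depth and named none.

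Alternatives covered a stricter level, the window for a match, the background of genes, the number of sites per gene, list length and the chromosomes used. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. On simulated data, independent lists the size of the YTHDF2-ADAR and YTHDF3-ADAR lists gave a ratio of 1.00 over 10478 genes. A planted common core of 1.13 was recovered as 1.13, and a planted level difference of 0.1 as 0.100 over 8991 genes.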

Results

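Sites edited by YTHDF1, YTHDF2 and YTHDF3, cytosolic proteins that bind m6A-modified mRNA, were mapped in HEK293T cells with each reader fused to ADAR or to APOBEC1. Cells received a pair of fusions, so each library contributed to 1 ADAR list and 1 APOBEC1 list. The 6 lists held 485050, 49331 and 37994 sites for YTHDF1-, YTHDF2- and YTHDF3-ADAR, and 93237, 34134 and 54778 for the matching APOBEC1 fusions. Each list is a single pooled set, so no value below has a replicate error, and the read depth behind each level is unknown.

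The YTHDF1 fusion had the most sites with either deaminase. YTHDF1-ADAR had 9.83 times as many sites as YTHDF2-ADAR and 12.8 times as many as YTHDF3-ADAR, against 2.73 and 1.70 times with APOBEC1. YTHDF2 had 1.30 times as many sites as YTHDF3 with ADAR and 0.623 times as many with APOBEC1, a difference that was not tested. The YTHDF2-ADAR list pooled 9 libraries and the YTHDF3-ADAR list 6, against 8 for each APOBEC1 list. YTHDF1-ADAR reached 15314 genes with a median of 21 sites per gene. The other lists held 7370 to 9361 genes with medians of 2 to 4 sites. A total of 4181 genes, 26.6% of the 15734 with any site, were in all 6 lists. Genes with the highest minimum over the 6 lists included the pseudogene transcript DUXAP10, the chromatin-associated ANKRD11 and the transcriptional repressor SPEN. DUXAP10 had 215, 37 and 29 ADAR sites and 71, 29 and 43 APOBEC1 sites for YTHDF1, YTHDF2 and YTHDF3. The corresponding numbers were 337, 38 and 38, then 43, 27 and 34, for ANKRD11, and 241, 24 and 23, then 68, 27 and 50, for SPEN. RBM12B, ZBED4, TASOR2, PDZRN3, KBTBD6, KLHL36 and PDE4DIP completed that group, each with at least 18 sites in every list.

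**Figure D1:**
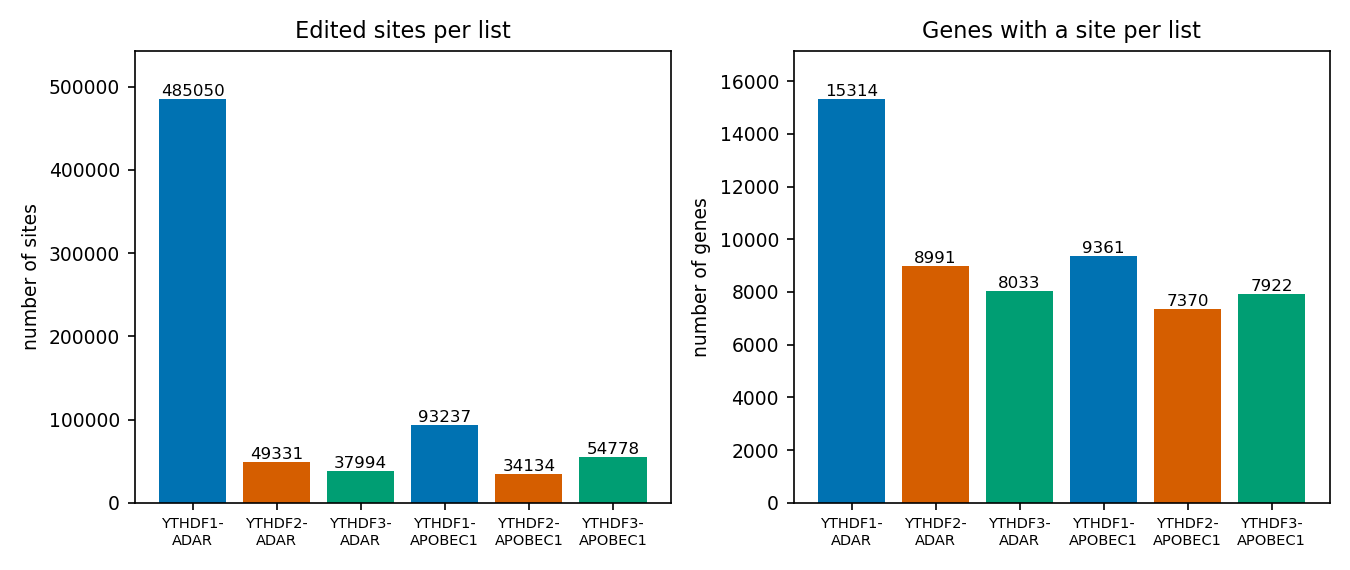
Number of edited sites (left) and of genes with a site (right) in the 6 deposited lists, 1 bar per fusion. YTHDF1-ADAR stands apart with 485050 sites and 15314 genes, and the other lists hold 34134 to 93237 sites.

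The ADAR and APOBEC1 fusions led with different genes. The cytoskeletal linker gene PLEC (chromosome 8, 143915153 to 143976745, GRCh38) had the most YTHDF1-ADAR sites, 423, with 53 and 51 for YTHDF2- and YTHDF3-ADAR, and 12, 3 and 7 with APOBEC1. The zinc finger gene ZNF853 (chromosome 7, 6615610 to 6624290) led both other ADAR lists with 76 and 60 sites, and had 230 for YTHDF1-ADAR and 4, 1 and 1 with APOBEC1. The cadherin gene FAT1 had 381 YTHDF1-ADAR sites, H6PD, an enzyme of the endoplasmic reticulum, had 379, and the planar polarity gene CELSR3 had 325. ZNF646, ZNF629, LRRC14, EMILIN3 and SON, which encodes a splicing cofactor, had 45 or more sites for YTHDF2- and YTHDF3-ADAR, except EMILIN3 with 40 for YTHDF3-ADAR. With APOBEC1, CREBZF and KCTD12, which encodes a subunit of GABA-B receptors, led for YTHDF2 with 84 sites each, and had 137 and 187 sites for YTHDF1. ARHGAP5, PABPC4L, OSBPL8 and CHML had 165, 154, 139 and 131 YTHDF1-APOBEC1 sites. Across 15734 genes, which are not independent replicates, site counts correlated at Spearman's rho of 0.722 to 0.864 between readers with the same deaminase and 0.398 to 0.569 between lists of different deaminases.

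With ADAR, almost all genes and sites of YTHDF2 and YTHDF3 were also in the YTHDF1 list. Of YTHDF2-ADAR sites 98.9% (95% interval 98.8 to 99.0) and of YTHDF3-ADAR sites 98.3% (98.2 to 98.4) were YTHDF1-ADAR sites, and 77.6% (77.2 to 78.0) of YTHDF3-ADAR sites were YTHDF2-ADAR sites. All 3 readers shared 7380 genes, 47.9% of 15399. Only 37 genes were in the YTHDF2-ADAR list alone and 28 in the YTHDF3-ADAR list alone, against 5775 in the YTHDF1-ADAR list alone. Relative to list length, YTHDF1-ADAR sites were most in excess over YTHDF2-ADAR in STARD9, a kinesin gene with 354 and 4 sites (7.30 and 0.811 per 10000), and in MACF1, a gene for a linker of microtubules and actin, with 261 and 2. ALMS1 had 276 and 4, LCOR 207 and 1, and TANC2 240 and 5. BAHCC1, RNF213 and PKD1, with 275, 244 and 295 YTHDF1-ADAR sites, had 6, 5 and 10 for YTHDF3-ADAR. In the other direction, ZNF853 had 15.4 per 10000 YTHDF2-ADAR sites and 4.74 per 10000 YTHDF1-ADAR sites, and SON had 11.6 and 3.94. WDR81, MZF1 and the calcium channel gene CACNA1H had 69, 47 and 31 sites for YTHDF2-ADAR against 38, 22 and 9 for YTHDF3-ADAR. HSPA6, a stress-inducible HSP70 gene, had 17 YTHDF3-ADAR sites and 0 for YTHDF2-ADAR, and KIAA1671 and TPPP had 20 and 21 against 5 and 7.

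Shared genes of YTHDF2- and YTHDF3-ADAR numbered 1.39 times those of independent lists (6116 against 4393), where 1.49 was the highest ratio possible. For YTHDF1-ADAR the ratio was 1.03 with either reader, and the highest possible was 1.04. Limited to its highest levels at the length of the shortest ADAR list, YTHDF1-ADAR shared 38.9% of sites with YTHDF2-ADAR and 34.9% with YTHDF3-ADAR. The design gives 1 set of control cells per deaminase, so part of the excess may come from those shared libraries. The expected number also treats all genes of N as equally likely to have a site. Differences between genes in expression or length, which were not matched, can therefore raise the ratio above 1 as well. Pairs of different readers and different deaminases averaged 1.313 after thinning, with the genes of all 6 lists as N.

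With APOBEC1, the readers shared most genes. YTHDF1-APOBEC1 held 70.4% (69.9 to 70.9) of YTHDF2-APOBEC1 sites and 71.7% (71.3 to 72) of YTHDF3-APOBEC1 sites, and YTHDF3-APOBEC1 held 56.6% (56.0 to 57.1) of YTHDF2-APOBEC1 sites. At the gene level the shares were 90.8, 92.8 and 83.0% of the shorter list, and 5985 of 10478 genes (57.1%) were in all 3 lists. Each APOBEC1 fusion was carried by its own stable cells, whose gene expression was not analysed. Differences between these lists in single genes therefore cannot be told from differences between the cells. Several genes had sites for YTHDF2-APOBEC1 but few or none for the other readers. DLG4 (chromosome 17, 7187187 to 7220050), which encodes the synaptic scaffold PSD-95, had 42 sites against 0 and 0 for YTHDF1 and YTHDF3. The alpha-tubulin gene TUBA4A had 37 against 0 and 0, the kinesin gene KIF5A 32 against 0 and 0, SLC22A17 32 against 1 and 1, and FBXL16 29 against 6 and 2. Other genes had lower values for YTHDF2 relative to list length. MANEA, a mannosidase gene of the Golgi, had 5.27 per 10000 YTHDF2-APOBEC1 sites against 16.1 and 19.5 for YTHDF1 and YTHDF3, and the transcription factor gene ONECUT2 had 3.81 against 11.9 and 13.5. The meiosis gene MEIOC had 0.879 against 8.47 and 9.86, BRWD1 6.15 against 13.6 and 12.2, the germ-cell gene TEX15 2.93 against 9.97 and 10.04, and P2RY1 3.81 against 10.5 and 12.4. YTHDF1 exceeded YTHDF3 per 10000 sites in PCNX1 (11.9 and 6.39), PDE4DIP, C5orf24, GEN1 and CCDC88A. YTHDF3 exceeded YTHDF1 in ABHD13, FOXO1, PPM1A and SHPRH.

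Observed over expected shared genes were 1.54, 1.58 and 1.66 for YTHDF1 with YTHDF2, YTHDF1 with YTHDF3 and YTHDF2 with YTHDF3. The highest possible ratios were 1.68, 1.68 and 1.99. N was 15399 genes here and 10478 for the ADAR pairs, so the ratios of the 2 deaminases are not on 1 scale. Limited to the highest levels at the same length, these pairs shared 30.8, 49.5 and 38.3% of sites. The APOBEC1 lists have 1 set of control cells too, and the expected number again treats all genes of N as equally likely to have a site.

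**Figure D2:**
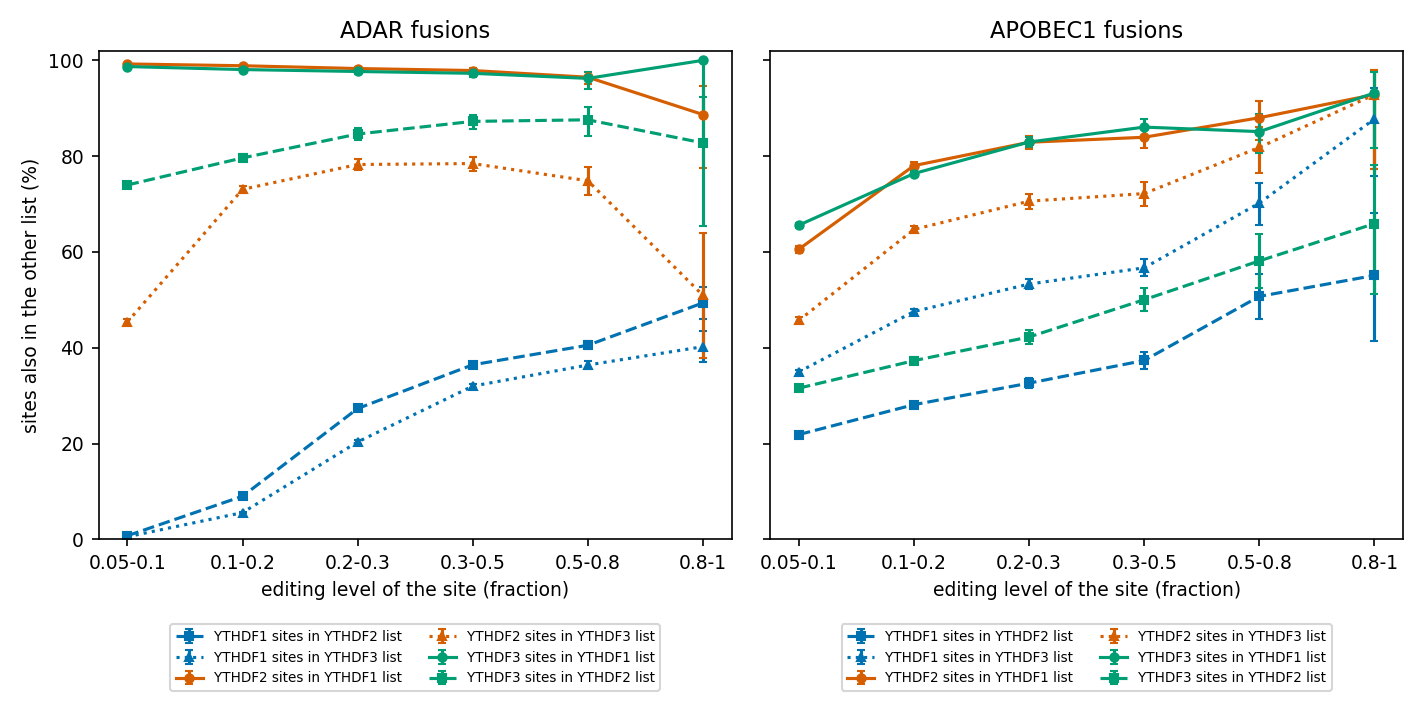
Percent of the sites of a list that are also in another list (y axis) by the editing level of the site, a fraction (x axis), for the ADAR fusions (left) and the APOBEC1 fusions (right). Colour gives the list the sites come from, line and marker the list searched, and bars the Wilson 95% interval. YTHDF1-ADAR sites were in the YTHDF2-ADAR list in 0.772% of cases at levels of 0.05 to 0.1 and in 49.4% at 0.8 to 1.

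Editing levels at shared sites were far higher for YTHDF1-ADAR than for the other ADAR fusions, and differed less between the APOBEC1 fusions. At the 29336 sites in all 3 ADAR lists the median level was 0.312 for YTHDF1, 0.118 for YTHDF2 and 0.0988 for YTHDF3. At the 17869 sites in all 3 APOBEC1 lists it was 0.120, 0.119 and 0.108. YTHDF1-ADAR exceeded YTHDF2-ADAR by a median of 0.155 (bootstrap 0.154 to 0.157) and was higher at 98.6% of 48785 sites. It exceeded YTHDF3-ADAR by 0.184 (0.182 to 0.185), being higher at 98.3% of 37351 sites. YTHDF2-ADAR exceeded YTHDF3-ADAR by 0.0182 (0.0177 to 0.0187), higher at 78.3% of sites. With APOBEC1, YTHDF1 exceeded YTHDF2 by 0.0006 (0.0001 to 0.0011), higher at 50.9% of sites. The median of the per-site differences within a gene was above 0 in 46.3% of genes. YTHDF1 and YTHDF2 exceeded YTHDF3 by 0.0079 (0.0076 to 0.0083) and 0.0072 (0.0067 to 0.0077), being higher at 63.8 and 61.8% of sites. Here the median difference within a gene was above 0 in 69.9 and 70.03% of genes. Over each list's own sites in single genes, PLEC had a median of 0.0985, 0.114 and 0.0920 for YTHDF1-, YTHDF2- and YTHDF3-ADAR. Shared sites are those at or above 0.05 in both lists, and with both at or above 0.1 the difference for YTHDF1 and YTHDF2 with APOBEC1 was 0.0034, and that for YTHDF2 and YTHDF3 with ADAR 0.0277.

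Shared genes were compared between an ADAR list and the APOBEC1 lists of the same and the other readers. After thinning, observed over expected shared genes averaged 1.322 for the same reader and 1.313 for other readers. The difference of 0.00918 had an SD of 0.00240 over 100 draws, which is the spread of the thinning alone. An exact permutation of the reader names gave p = 0.333 (two-sided, 6 orders), with the real order the highest of the 6. It was the highest under the 4 alternatives too, with differences of 0.0128 to 0.0259 and two-sided p of 0.167, the smallest possible, in 3 of them and 0.333 in 1. YTHDF1 had 1.25 with itself and 1.24 and 1.25 with YTHDF2- and YTHDF3-APOBEC1. YTHDF2-ADAR had 1.33 with each APOBEC1 list, and YTHDF3-ADAR had 1.39 with YTHDF3-APOBEC1 against 1.38 and 1.35. The same reader was not always the best match. YTHDF2-ADAR had 1.332 with YTHDF3-APOBEC1 against 1.329 with its own reader. Unthinned, YTHDF1-ADAR had 1.002 with its own reader against 1.009 and 1.004, and YTHDF3-ADAR had 1.334 against 1.340 with YTHDF2-APOBEC1. The alternatives reuse the same 6 lists. Every library entered a list of each deaminase, and with 3 readers no p under 0.05 could be had.

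APOBEC1 sites lay closer to the 3′ ends of genes than ADAR sites did. Of sites in protein-coding spans, 53.9% (bootstrap over genes 52.6 to 55.3), 58.3% (56.8 to 59.8) and 53.3% (51.8 to 54.8) lay in the last 2 kb for YTHDF1-, YTHDF2- and YTHDF3-APOBEC1. For the ADAR fusions these shares were 32.3% (31.8 to 32.9), 36.9% (35.8 to 38.1) and 34.4% (33.3 to 35.6). Chromosome 19, which is dense in short genes and zinc finger genes, held 6.89 to 8.09% of ADAR sites and 3.96 to 4.33% of APOBEC1 sites. Chromosome 13 held 1.31 to 1.65% and 3.73 to 4.0%. Protein-coding genes held 91.3 to 94.7% of the sites of every list, and long noncoding RNAs 1.73 to 2.89%. The last 2 kb can hold coding sequence, and spans do not separate exons from introns.

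**Figure D3:**
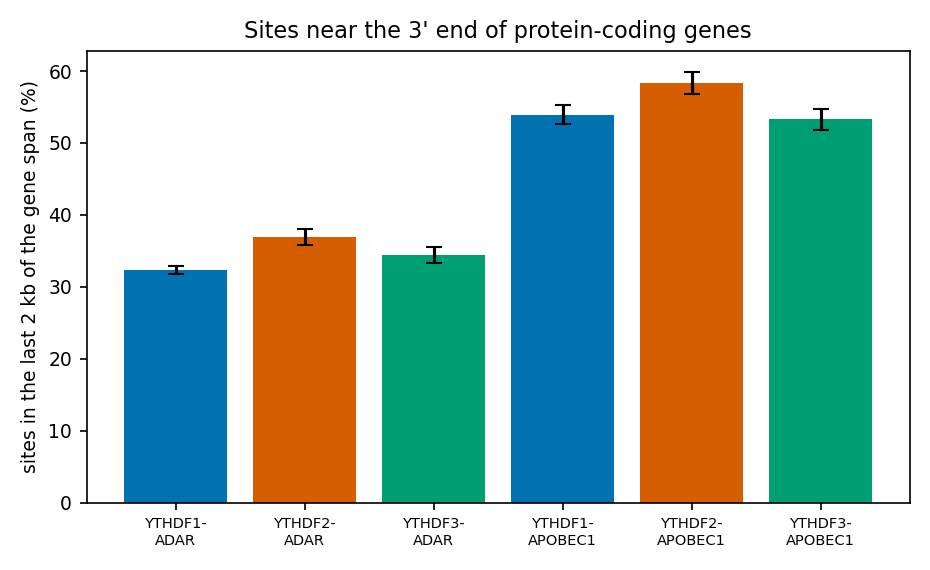
Percent of the sites in protein-coding gene spans that lie in the last 2 kb of the span (y axis), 1 bar per fusion, with 95% bootstrap intervals over genes. The APOBEC1 bars stand at 53.3 to 58.3% and the ADAR bars at 32.3 to 36.9%.

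Zinc finger genes and chromatin regulators had sites more often than random genes of like span. Transcript length and expression were not matched. An excess or deficit, here and for the gene lists below, cannot be told from a difference in these. Of 385 ZNF genes with a site in any list, 321 and 327 (83.4 and 84.9%) had a YTHDF2- and YTHDF3-ADAR site, against 61.6 and 54.8% in random lists. With APOBEC1, 341, 270 and 306 had sites (88.6, 70.1 and 79.5% against 61.3, 49.6 and 51.7%), so 5 of 6 lists exceeded the middle 95% of random lists. The sixth, YTHDF1-ADAR, reached 383, or 99.5% against 99.2% in random lists. That list holds most genes of this background, so it had little room to exceed random lists here or below. ZNF678 had 140, 48 and 95 APOBEC1 sites and ZNF451 had 101, 35 and 78. Of 48 chromatin regulators, 37 and 40 had YTHDF2- and YTHDF3-ADAR sites and 41, 37 and 37 had APOBEC1 sites, above the middle 95% in 3 of 6 lists. ASXL1, a Polycomb-associated gene, had 173, 44 and 34 ADAR sites, and the methyltransferase genes KMT2C and NSD1 had 50 and 25 YTHDF1-APOBEC1 sites. Of the 13 genes of m6A writers and erasers, 11 had a site in the YTHDF2-ADAR list and in each APOBEC1 list and 9 in the YTHDF3-ADAR list, above the middle 95% for YTHDF2- and YTHDF3-APOBEC1, though inside it when 2 sites per gene were required (percentiles 91.5 and 95.1). RBM15B and ZC3H13, partners of the m6A methyltransferase, had 188 and 70 YTHDF1-ADAR sites and 28 and 69 YTHDF1-APOBEC1 sites.

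Outside YTHDF1-ADAR, genes of energy metabolism and of histones had sites less often than random genes of like span among those with a site in any list. Genes of ribosomal proteins did so with ADAR only. Both results depended on the background. Set against all annotated genes of the same class (protein-coding, or long noncoding RNA for that list), with or without a site, 15 of the 19 shares below the middle 95% (here and in the next paragraph) came inside it and 1 turned to the opposite side. The 11 shares above it stayed above, and 34 further shares came to lie outside it. Of 68 genes of oxidative phosphorylation, 21 and 18 had YTHDF2- and YTHDF3-ADAR sites (30.9 and 26.5% against 61.8 and 54.4%) and 18, 12 and 15 had APOBEC1 sites (26.5, 17.6 and 22.1% against 55.9, 45.6 and 47.1%), below the middle 95% in 5 of 6 lists. When 2 sites per gene were required, YTHDF1-ADAR fell below it too, with 48 of these genes (70.6% against 95.6%). NDUFB9, NDUFV3 and NDUFS7, subunits of complex I, had 72, 53 and 47 YTHDF1-ADAR sites but at most 8 in the other ADAR lists. Of 37 genes of glycolysis and the citrate cycle, 11 and 7 had YTHDF2- and YTHDF3-ADAR sites and 11, 16 and 9 had APOBEC1 sites, below in 4 lists. OGDH and HK2 had 9 and 6 YTHDF1-APOBEC1 sites. Replication-dependent histone genes were below in 4 lists, with 10, 8, 7, 4 and 8 of 29 in the lists other than YTHDF1-ADAR. When 2 sites per gene were required, YTHDF2-APOBEC1 came inside (percentile 3.54), and YTHDF1-ADAR and YTHDF3-APOBEC1 fell below (0.135 and 1.57). Their transcripts mostly lack poly(A) tails, and the libraries were made from poly(A) RNA. A low share of these genes can therefore not be told from loss of their RNA from the libraries. Of 76 cytosolic ribosomal protein genes, 63, 24 and 26 had an ADAR site (82.9, 31.6 and 34.2% against 98.7, 60.5 and 53.9%), all below the middle 95%. With APOBEC1, 42, 32 and 38 had one (55.3, 42.1 and 50% against 50, 39.5 and 42.1%), inside it. The difference between the deaminases was not tested. All 3 APOBEC1 shares stood at percentile 100 against all annotated genes, and YTHDF2-APOBEC1 was below the middle 95% with at least 2 sites (percentile 1.0). RPL28 had 67 YTHDF1-ADAR and 7 YTHDF1-APOBEC1 sites, and RPS24 had 46 and 4. The share that turned was the ribosomal list for YTHDF1-ADAR, at percentile 100 against all annotated genes. Those that stayed below were oxidative phosphorylation for YTHDF1- and YTHDF2-APOBEC1 and glycolysis with the citrate cycle for YTHDF3-ADAR.

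**Figure D4:**
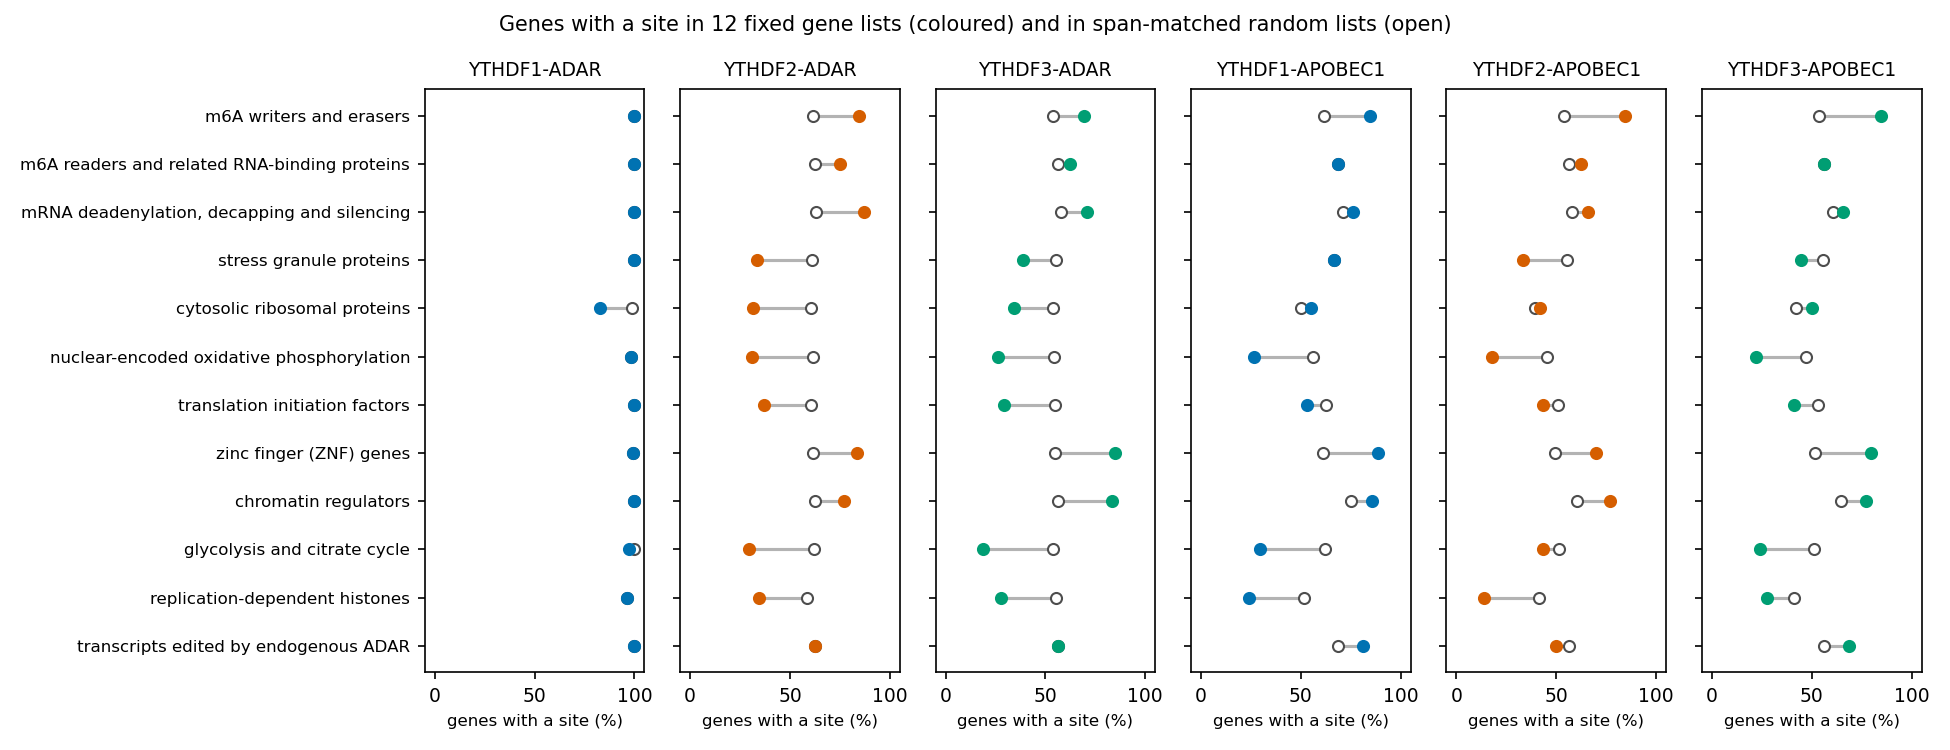
Percent of the genes of 12 fixed lists that have a site (coloured points) and the median of 10000 random lists matched on gene span (open points), 1 panel per fusion. Genes of oxidative phosphorylation lie at 17.6 to 30.9% in the 5 lists other than YTHDF1-ADAR, and zinc finger genes at 70.1 to 88.6%.

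Of 38 genes of mRNA deadenylation, decapping and silencing, 33 had a YTHDF2-ADAR site (86.8% against 63.2%), above the middle 95%. YTHDF3-ADAR lay just inside it with 27 (percentile 96.5), and the APOBEC1 lists lay inside with 29, 25 and 25 (71.4 to 80.3). Against all annotated genes all 6 lists were above it (percentiles 99.5 to 100), and no test compared the lists. TNRC6A, a partner of Argonaute proteins, had 24 YTHDF2-ADAR and 16 YTHDF3-ADAR sites, and the exonuclease gene XRN1 had 2 and 1, with 39, 20 and 29 APOBEC1 sites. Stress granule genes were below for YTHDF2-ADAR, with 6 of 18 (33.3% against 61.1%), but inside the middle 95% with at least 2 sites (percentile 6.52) and against all annotated genes (19.0). With at least 2 sites, YTHDF3-ADAR and YTHDF3-APOBEC1 were below instead (2.16 and 1.27). TIAL1 had 39, 13 and 35 APOBEC1 sites. Of 51 genes named EIF, 19 and 15 had YTHDF2- and YTHDF3-ADAR sites (37.3 and 29.4% against 60.8 and 54.9%), below the middle 95% but inside it against all annotated genes (percentiles 20.1 and 9.59). With APOBEC1, 27, 22 and 21 had sites, inside it, but with at least 2 sites YTHDF1-APOBEC1 and YTHDF3-APOBEC1 were below it (1.78 and 0.765). The kinase gene EIF2AK4, caught by its name, led that list with 75 YTHDF1-ADAR sites, and the scaffold gene EIF4G1 had 73. Among 16 genes of m6A readers and related proteins, 9 to 12 had sites outside the YTHDF1-ADAR list, and known targets of endogenous ADAR numbered 8 to 13 of 16. Both groups lay inside the middle 95% in every list in this background. For YTHDF1-ADAR they could not lie above it, since random lists had a median of 100%. Nuclear-retained noncoding RNAs were few (4 in the comparison), and TUG1 had 103 YTHDF1-ADAR and 75 YTHDF1-APOBEC1 sites. The 15 mitochondrially encoded mRNAs and rRNAs had 0 sites in all 6 lists, counted by position. A mitochondrial transfer RNA, MT-TK, had 1 site each for YTHDF1-ADAR and YTHDF2-ADAR, at levels of 0.0519 and 0.0531. Of 18 markers of other cell types, COL1A1 and EPCAM alone had sites, at most 2 per gene with APOBEC1 and 0 for YTHDF2- and YTHDF3-ADAR, while COL1A1 had 17 for YTHDF1-ADAR.

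Counts follow for the genes of the readers and of ADAR and APOBEC1 enzymes. YTHDF2 had 0.969, 0.405 and 1.05 per 10000 ADAR sites of the YTHDF1, YTHDF2 and YTHDF3 fusions. YTHDF3 had 4.83, 4.10 and 3.83 per 10000 APOBEC1 sites. In numbers of sites, YTHDF1 had 35, 3 and 3 ADAR sites and 15, 5 and 2 APOBEC1 sites for the YTHDF1, YTHDF2 and YTHDF3 fusions. YTHDF2 had 47, 2 and 4, then 1, 1 and 0, and YTHDF3 had 62, 3 and 3, then 45, 14 and 21. ADARB1 had 115, 14 and 8 ADAR sites, ADAR 92, 14 and 9, and the human APOBEC1 gene had 0 in all lists. The vector sequence is labelled RtApobec and is separate from the human gene, so that 0 does not bear on the plasmid. Which gene gave the ADAR domain was not determined here. YTHDF2P1 (chromosome 14, 39215064 to 39217159), a pseudogene of YTHDF2, had 18 YTHDF2-ADAR sites against 6 and 0 for YTHDF1- and YTHDF3-ADAR, and 1, 0 and 2 with APOBEC1. Reads from YTHDF2, its pseudogene and the plasmid share sequence, so the origin of those sites is uncertain.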

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

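A signal outside the genome was found in the lists, on a vector sequence that the deposited lists name after APOBEC1 and that no comparison above used. All 24 libraries with 2 fusions held an APOBEC1 fusion, so reads from the fusion itself can give such sites. YTHDF1-ADAR had 11 sites on it, above the 3 used as the limit for flagging a list, and YTHDF2-ADAR had 2 and YTHDF3-ADAR 0. Relative to list length this was no excess for YTHDF1-ADAR, with 0.227 per 10000 sites against 0.405 for YTHDF2-ADAR. The sites at positions 747 and 749 had levels of 0.594 and 0.600 for YTHDF1-ADAR and 0.517 and 0.584 for YTHDF2-ADAR. With APOBEC1 the site at position 751 was in all 3 lists, at 0.410, 0.464 and 0.408 for YTHDF1, YTHDF2 and YTHDF3.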

How the results depend on the processing

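The last 2 kb measure, its limit to genes of at least 20 kb, and both settings for levels were chosen after seeing the data. Pairs are given in the order YTHDF1 with YTHDF2, YTHDF1 with YTHDF3 and YTHDF2 with YTHDF3, ADAR before APOBEC1, and lists likewise by reader. The cause of each shift was not tested, except where a setting removes sites by construction. Gene numbers stayed within 1.5 times under the stricter level (sites at or above the list median) and on chromosomes 1 to 22 and X. The stricter level left 242664, 24695, 19010, 46667, 17074 and 27423 sites by construction. Shared sites were then 98.2, 97.2, 77.0, 68.5, 69.6 and 55.4% of the shorter list. Within 50 nt they were 99.3, 98.9, 83.3, 85.9, 88.5 and 76.7%. Thinned to the shortest list they were 7.76, 7.70, 59.8, 25.8, 26.3 and 35.2%, values that the list lengths and the unthinned overlap fix by construction, and from the highest levels 38.9, 34.9, 69.2, 30.8, 49.5 and 38.3%. Observed over expected shared genes stayed above 1 throughout. They were 1.05, 1.05, 1.64, 1.91, 1.95 and 2.11 at the stricter level and 1.05, 1.06, 1.78, 1.99, 2.07 and 2.27 with at least 2 sites per gene. Thinned they were 1.16, 1.16, 1.42, 1.69, 1.81 and 1.72, and from the highest levels 1.19, 1.19, 1.44, 1.69, 2.0 and 1.72. Against the union of all 6 lists they were 1.02, 1.02, 1.61, 1.53 and 1.56, and 1.65 for the last pair. The same-reader difference was positive under all 4 alternatives, 0.0128 to 0.0259, with no p under 1/6 possible. The last 2 kb held 32.8, 36.2, 57.2, 61.3 and 56.7% at the stricter level, and 34.4% for YTHDF3-ADAR. With genes weighted equally it held 38.6, 39.0, 36.6, 62.1, 62.2 and 60.5%, and in genes of at least 20 kb 25.9, 27.9, 25.6, 50.6, 55.3 and 49.6%. Level differences with at least 0.1 in both lists were 0.205, 0.240, 0.0277, 0.0034, 0.0112 and 0.0066. Of 84 gene-list percentiles, 71 kept their side of the middle 95% with at least 2 sites, with 9 newly outside it and 4 no longer so. Against all annotated genes 34 kept it, 34 were newly outside and 15 no longer so, and the ribosomal list for YTHDF1-ADAR turned to percentile 100. No paired analysis was possible because the lists are pooled and carry no replicate numbers, so leaving out replicates or a replicate block was not run either. Alternatives on coverage, exonic sites, 3′ UTRs and the DRACH motif were not run, since depth and exons were not analysed here. The unknown depth limits every level.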

Other observations

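The genes and thresholds of the next paragraph, and the tests of a lower floor, of sequencing depth and of a factor of any size in the one after it, were chosen after the values were seen.

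Genes with many sites in a single APOBEC1 list were nearly all in the YTHDF2-APOBEC1 list, although that list was the shortest. With at least 10 sites in a list and 0 in both others, there were 14 genes for YTHDF2-APOBEC1, 3 for YTHDF1-APOBEC1 and 0 for YTHDF3-APOBEC1. Besides DLG4, TUBA4A and KIF5A, the 14 included AGAP2 with 26 sites, the postsynaptic scaffold gene DLGAP3 with 25 and NDRG4 with 23. ALDOC, PDE1B and RUNDC3A had 17 each, the dynamin gene DNM1 14, and ARHGAP33 and the potassium channel gene KCNJ4 10 each. These 12 named genes had YTHDF1-ADAR sites, from 6 in ALDOC to 70 in KCNJ4, a list pooled over all 3 APOBEC1 cell lines. YTHDF2-ADAR did not set these genes apart from YTHDF3-ADAR in the same way. Those 2 lists had 0 and 0 sites in DLG4, ALDOC and DNM1, 1 and 2 in KIF5A, and 2 and 8 in DLGAP3. TUBA4A had 9 and 3, AGAP2 4 and 2, NDRG4 and PDE1B 1 and 0. RUNDC3A had 0 and 1, ARHGAP33 0 and 2, and KCNJ4 25 and 25. The 3 YTHDF1-APOBEC1 genes were MTUS2-AS1, CCDC146 and ADAMTS20, with 13, 11 and 10 sites. The expression of these genes in each line was not analysed here.

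The YTHDF1-ADAR list was several times longer than the YTHDF2- and YTHDF3-ADAR lists. A lower floor was argued against, since the lowest level was 0.05 in all 3 lists, and so was depth alone, since YTHDF1-ADAR had the higher level at no less than 98.3% of shared sites. A common factor on the editing odds, of any size, was argued against as the whole cause, since a factor under 19 would leave all 15238 YTHDF1-ADAR sites at 0.5 or more past the floor, where 41.0% were in the YTHDF2-ADAR and 36.6% in the YTHDF3-ADAR list, and a larger one would leave fewer than the 48785 and 37351 shared sites. The 167532 sites left by the median factor at sites shared with YTHDF2-ADAR, 3.11, decide nothing, since sites past the floor in both lists make that factor too low. What stays open is a different calling or pooling of that list, a higher amount of the YTHDF1-ADAR protein joined with lower depth or fewer reads at single sites elsewhere, and wider binding by YTHDF1, which may each contribute and were not tested.

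The APOBEC1 lists shared part of their sites although levels at shared sites differed by a median of at most 0.0079. If sites near the floor of 0.05 fell to either side of it by chance, those at 0.2 or more should nearly all be shared. The shares of such sites in the other list went down to 34.6% (YTHDF1 sites in the YTHDF2 list), and 4 of the 6 shares were under 75%, which argues against the floor as the whole cause. Each APOBEC1 fusion was carried by its own stable cells. Depth per site, gene expression or the amount of fusion in those cells, and a difference in binding between the readers stay open and were not tested.

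Sites with a level of 0.8 or more were enriched in pseudogenes, most of all with APOBEC1. Of 49, 28 and 44 such APOBEC1 sites, 40.8, 35.7 and 38.6% lay in pseudogenes for YTHDF1, YTHDF2 and YTHDF3, against 1.09 to 1.33% of other sites. With ADAR the shares were 3.54% of 875 sites, 9.43% of 53 and 20.7% of 29. The lowest of the 6 ratios was 1.92, for YTHDF1-ADAR, where reads shared between a gene and its copy may account for few of the sites. For the APOBEC1 lists such reads remain a candidate source, and no biological explanation was tested.

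A hypothesis that the deaminases edit the same stretches of RNA was tested by distance. Within 50 nt of an ADAR site of the same reader lay 43.4% of YTHDF1-APOBEC1 sites, 7.73% of YTHDF2-APOBEC1 sites and 6.12% of YTHDF3-APOBEC1 sites. After a shift of 500 nt the shares were 38.1, 7.44 and 6.69%, ratios of 1.14, 1.04 and 0.915. Local clustering had been set to need a ratio of 1.5 for all 3 readers, and its absence a ratio under 1.1 for all 3, and neither was met. The shift followed genome coordinates without regard to exons. Shifted positions can thus fall outside mature transcripts, which can raise the ratio without local clustering. YTHDF1 had a small excess by this measure and the other readers had none of that size, so the question stays open. Pooled lists do not show whether sites lie on the same molecule.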
